A study of Mus musculus with 2 samples.

How the data were processed

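Single-cell RNA sequencing was performed on dissociated testes of mouse embryos at embryonic day E16.5, from wild-type animals of the CD-1 strain that carried a transgene named for Nr5a1 and green fluorescent protein (GFP). Per the labels' protocols, tissue was treated with 0.05% trypsin-EDTA for 10 min at 37 °C, 3000 to 7000 cells were loaded on a droplet device that tags the 3' end of each transcript with a cell barcode and a unique molecular identifier (UMI), and libraries were read as pairs of 26 and 98 bases with a target of 100000 to 150000 reads per cell. The series holds 1 group with 2 captures, which the labels call independent replicates sequenced on different runs. They are numbered 1 and 2 here in accession order. Nothing in the labels says that the captures came from separate animals. The p-values below measure how far differences between classes vary over these 2 captures, once the overall difference between captures is taken out. That spread may be technical.

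The authors deposited a table of raw UMI counts per gene and cell for each capture, and a second table of values on a natural log scale. Cell Ranger 2.1.0, Seurat 2.3 and genome build GRCm38.p5 are named per the submitters' processing notes, with no role or order, and the filters that set which cells and genes were kept are not given in the sources used here. The deposited natural log values were recomputed as the log of 1 plus the count scaled to 10000 UMIs per cell. All 83487645 values of capture 1 and 138724065 values of capture 2 matched within 1e-09, so the log tables held no information beyond the counts and only the counts were used. The authors also deposited their gene annotation with a GFP contig added. Of 23445 genes in the tables, 23427 were found in it by name, 25 of the names with more than 1 annotated gene. Coordinates are those of this annotation, counted from 1.

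Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 2 cells of capture 1 and 5 of capture 2. Scrublet, run in scanpy 1.11.5 with an expected doublet rate of 3%, called 0 and 1 doublets. These counts do not tell whether doublets were removed before deposit or missed here. Cells that share a droplet may therefore remain among those analysed. In total 3559 and 5911 cells were kept. Both captures were clustered together without correction between them, on 2000 highly variable genes, values scaled to at most 10, 30 principal components, 15 neighbours and the Leiden method (igraph 0.11.9) at resolution 1, which gave 20 clusters. All 470 detected members of the gene lists named below, GFP, Xist, Tsix, and mitochondrial and ribosomal protein genes were kept out of the clustering.

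A cluster was called X-like from marker genes fixed before the data were examined, of which 136 were in the tables. It needed at least 3 markers at least 2-fold above the mean of the clusters that scored best for another type. It also needed a mean marker log2 ratio of at least 0.5, and no other type with more markers among its 10 leading genes. A last condition was set after seeing the data: a cluster needed more than 50% of the marker count of the best cluster of its type. It replaced a score-based condition tried first, and it left 1 stromal cluster of 8.20% and 7.43% of cells without a name. Stress and immediate early genes were among the leading genes of 2 interstitial progenitor-like clusters, Jund and Klf2 in the cluster mostly of capture 1 and Fosb, Maff and Egr3 in the cluster mostly of capture 2. No cluster was named for red blood cells or for neural cells.

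Raw UMI counts were summed per capture and class. Classes with under 20 cells in a capture were left out of the fit, which removed the white blood cell-like and the duct or rete epithelium-like classes. The remaining 8 classes gave 16 sums of 685276 to 22170186 UMIs. These were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3, with capture as a block and class as the factor, which left 7 residual degrees of freedom. The block was written into the design because all classes of a capture share a dissociation and a library. Each class was compared with the unweighted mean of the log expression of the other classes, so a fold is against a geometric mean. Of 18183 genes that passed the filter, 1822 had been used for clustering or naming and were not tested as results, leaving 16361. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Levels are TMM-scaled CPM of UMIs, computed here from the deposited counts, as mean ± SD over the 2 captures, n = 2 throughout. CPM without TMM scaling is used for sums of the G2 and M list, ratios between captures, free RNA and marker ratios. It is also used for cells outside the fit and for single clusters outside the tested contrasts. In data simulated for the Sertoli-like contrast on 14391 genes, the same code recovered 66 of 90 genes changed 2-fold (73.3%) and 82 of 87 changed 4-fold (94.3%), with 10 of 158 calls on unchanged genes. In the simulation all classes had the same mean profile apart from these changed genes, raised and lowered in equal numbers. The capture effect was the same in every class. The real contrast called 4555 genes higher and 2704 lower, so these rates may not hold for it.

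The 20 gene lists were fixed before the data were examined. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Named genes follow a rule fixed at the same time. In the Sertoli-like contrast these are Pten, up to 8 called members of the PTEN-PI3K-AKT list and of the insulin and IGF list by size of change, 2 members of every other list, all with at least 20 CPM in the highest class, and 4 genes higher and 4 lower outside the lists with at least 50 CPM in the highest class. Every other class has 6 list members, and GFP and Nr5a1 are always given. Under this rule a gene other than Pten, GFP and Nr5a1 had to pass the threshold with the same sign in both captures. Members named because a count was 5 or fewer, the single genes named within the cell cycle and PI3K lists beyond that rule, and all genes of contrasts between clusters were chosen after their values were seen. Cell cycle shares were counted after thinning each cell to 3000 UMIs, and no cell was shallower than that. Share intervals are exact binomial 95% intervals and cover counting error only. For a gene with no UMI in a class, the bound on its fold is the arithmetic mean CPM of the other classes over a floor of 3 UMIs in the class, so it is not on the scale of the folds against a geometric mean. Where a class that enters the mean of the others had 3 or fewer UMIs of a gene, the fitted fold depends on the prior count, so its CPM is given beside the arithmetic mean CPM of the other classes instead.

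The counting of strand is not given in the sources used here. Of 89 named genes, 6 had another annotated gene on the same strand inside or across them (Bicc1, Bnc2, Lama2, Mgll, Ntrk1 and Pik3c2a) and 17 had 1 on the opposite strand, Igf2, Igfbp7 and Inppl1 among them, so the levels of these genes are uncertain to that extent. Alternatives comprised RLE and total-count scaling, no filter on low counts, no replicate block, DESeq2 1.42.0, sums thinned to the smallest total, clustering at resolutions 0.5 and 2, centring within each capture, no filter on genes or mitochondrial UMIs per cell (called doublets still removed), called doublets kept, each capture left out, fits of 2 classes alone, and other depths and minimums for the cell cycle share. After seeing the data, 3 more were added: removing the highest 5% of doublet scores, naming without the last condition, and removing 2 clusters low in mitochondrial UMIs.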

Results

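The transcriptomes of single cells from the fetal mouse testis at embryonic day E16.5 were recorded in 2 captures of 1 group. Capture 1 held 3561 cells with 42337563 UMIs, a median of 10064 UMIs and 3329 genes per cell. Capture 2 held 5917 cells with 66555770 UMIs, a median of 9371 UMIs and 3143 genes per cell. The title of the series concerns PTEN, a lipid phosphatase that opposes PI3K signalling, in the proliferation of Sertoli cells, the supporting cells of the seminiferous cords. All animals were wild type, so the comparisons open to these data lie between the cell classes within the captures.

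Interstitial progenitor-like cells made up the largest part of the cells kept, 42.8% ± 1.92 (SD, n = 2 captures). That share rested on the clustering in capture 2, where it was 41.4% but 26.7% at clustering resolution 2 and 23.4% without the filters on genes and mitochondrial UMIs, under the 27.7% and 25.5% of cells then left unnamed in that capture. Sertoli-like cells made up 20.3% ± 0.528, with 19.9% (95% interval 18.6 to 21.2) in capture 1 and 20.6% (19.6 to 21.7) in capture 2. Peritubular myoid-like cells, the contractile cells around the cords, made up 12.1% ± 0.189, fetal Leydig-like cells 5.30% ± 0.825 and germ-like cells 5.08% ± 0.427. Surface epithelium-like cells followed with 2.62% ± 0.321, pericyte-like cells with 2.21% ± 0.388 (0.887% when genes were centred within captures) and endothelial-like cells with 0.875% ± 0.233. White blood cell-like cells numbered 15 and 36 in the captures, and duct or rete epithelium-like cells 18 and 21. These are shares of captured droplets after enzymatic dissociation, and no test was run on them. An unnamed stromal cluster held 7.82% ± 0.550 of the cells, and the peritubular myoid-like share was 22.3% at clustering resolution 0.5, 6.62% at resolution 2 and 19.9% without the naming condition that was set after seeing the data.

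Sertoli-like cells differed from the mean of the other 7 classes in a broad set of genes. Outside the gene lists, Eps8, an actin-capping protein, had 59.7 ± 3.32 CPM against 7.51 in the mean of the other classes, Trim62 was 9.75-fold higher (68.1 ± 11.1 CPM) and Spock2, a matrix proteoglycan, was 8.89-fold higher (107 ± 8.94 CPM). Abcg1, a sterol transporter, passed as higher at 13.1 ± 0.666 CPM, but endothelial-like cells had 57.9 CPM of it. Among the lowest, Mgll, which breaks down monoacylglycerols, was 29.7-fold lower, Bnc2 15-fold, Bicc1 14.2-fold and Gypc 13.0-fold. Of 16361 genes tested, 4555 were higher and 2704 lower (edgeR quasi-likelihood, Benjamini-Hochberg), 1958 and 1317 of them by at least 2-fold. The same sign in both captures was a condition for naming the genes above, so their agreement between captures is not a result. The split moved with the scaling: the share of calls that were higher was 62.8% with TMM, 54.1% with RLE (3855 higher, 3276 lower) and 49.6% with DESeq2 (3512 higher, 3562 lower), and the median log2 of all tested genes was 0.09, −0.02 and −0.11, a shift to be kept in mind for small folds. Most Sertoli-like cells of capture 1 lay in a cluster of their own (616 of 708), and those of capture 2 in 2 others (634 and 365 of 1220).

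UMIs of Pten were found in all 8 classes, and its level in Sertoli-like cells did not pass the test against the mean of the other classes. It is a protein-coding gene (ENSMUSG00000013663.7) on chromosome 19, from 32757497 to 32826160 on the plus strand, with no annotated gene across it. Sertoli-like cells had 43.0 ± 7.83 CPM of Pten, from 361 and 505 UMIs, a level 1.03-fold that of the other classes (95% interval 0.847 to 1.26; log2 0.05, SE 0.141, adjusted p = 0.875). The class means ran from 28.9 ± 5.27 CPM in germ-like cells to 60.5 ± 21.6 CPM in pericyte-like cells. Interstitial progenitor-like cells had 46.7 ± 24.3 CPM, fetal Leydig-like cells 46.6 ± 3.11, endothelial-like cells 43.7 ± 27.3, peritubular myoid-like cells 41.4 ± 18.5 and surface epithelium-like cells 35.8 ± 6.27. Capture 1 had the higher Pten level in every class of the fit, by most in endothelial-like cells (63.0 against 24.4 CPM, from 42 and 17 UMIs). Free RNA was not subtracted from these levels: in the classes other than fetal Leydig-like, 5 Leydig marker genes stood at 5.01% to 28.4% of their level over all cells of the capture (median gene), and at 28.4% and 27.3% in germ-like cells.

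Against the other classes taken singly, germ-like cells were the only class of the fit in which Pten passed the test. Sertoli-like cells had 1.49-fold more Pten than germ-like cells (95% interval 1.14 to 1.94; log2 0.57, adjusted p = 0.0343 over the 7 classes and 0.00737 over all genes, edgeR). The log2 differences to the other 6 classes lay between −0.45 for pericyte-like cells (adjusted p = 0.197) and 0.25 for surface epithelium-like cells (adjusted p = 0.613). The call against germ-like cells was fragile. It stayed past the threshold in 8 of 15 alternatives, with adjusted p-values from 0.00150 to 0.968, and was lost with RLE scaling (log2 0.19, adjusted p = 0.732), with total counts (0.37, 0.199) and with DESeq2 (0.19, 0.823).

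**Figure D1:**
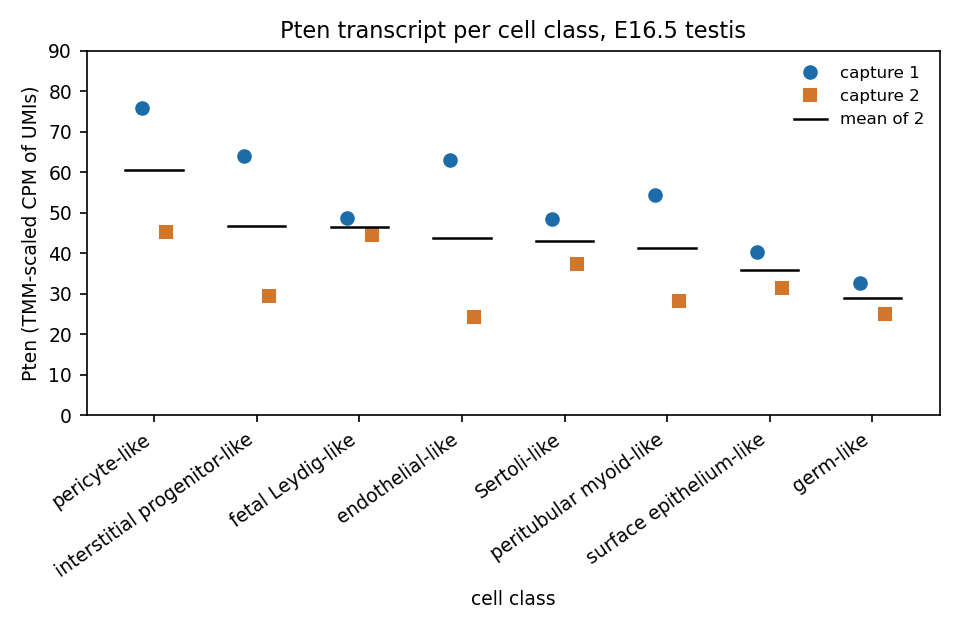
Pten in TMM-scaled CPM of UMIs (vertical axis) in each of the 8 cell classes of the fit, with a circle for capture 1, a square for capture 2 and a horizontal line for the mean of the 2 captures. Class means lie between 28.9 CPM in germ-like and 60.5 CPM in pericyte-like cells, and the Sertoli-like mean of 43.0 CPM lies among them.

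Genes of the PTEN-PI3K-AKT pathway went both ways in Sertoli-like cells. The forkhead transcription factors that AKT restrains were among the higher ones: Foxo6 was 6.48-fold higher (36.4 ± 27.1 CPM) and Foxo3 3.67-fold higher (84.9 ± 23.0 CPM), whereas Foxo1 had 30.2 CPM against 36.8 in the mean of the other classes and did not pass. Inppl1, the lipid phosphatase SHIP2, was 2.63-fold higher (71.7 ± 6.84 CPM) and Pik3c2a, a class II PI3-kinase, 2.52-fold higher (43.7 ± 3.59 CPM). Other kinase subunits were scarce: Pik3cd was 4.76-fold lower (1.15 CPM) and Pik3r3 2.61-fold lower (2.28 CPM), Pik3c2b had 0.700 CPM against 25.1 in endothelial-like cells, and the phosphatase Inpp4b had 3 UMIs in capture 1 and 0 in capture 2, against 20.8 CPM in pericyte-like cells. Akt1 was also lower (log2 −0.62, adjusted p = 2.63e-04), at 68.6 CPM against 138. In all, 8 of 28 members were higher and 8 lower, and the same counts held adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.693, leaning down), while fry, which does not compare a list with other genes, called it up (adjusted p = 0.0203); its median log2 was 0.08, its mean −0.08. The calls of Inpp4b (adjusted p = 1.0), Pik3c2b (0.995), Pik3cd (1.0) and Pik3r3 (0.171) were lost in sums thinned to the smallest total, and thinning left 4 members higher and 1 lower.

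Insulin-like growth factors and their binding proteins were low in Sertoli-like cells. Igf2, a fetal growth factor, was 12.8-fold lower (7.20 ± 1.79 CPM) and Igf1 5.96-fold lower (10.6 ± 0.209 CPM). The binding proteins that hold these factors outside cells followed: Igfbp2 was 16.0-fold lower, Igfbp4 9.31-fold, Igfbp5 9.27-fold and Igfbp7 5.66-fold. The size for Igfbp7 differed between the captures (log2 −2.02 and −3.45). The RNA-binding protein gene Igf2bp1 was 14.1-fold lower and the adaptor Grb10 5.35-fold lower. The receptors Igf1r (log2 0.21, adjusted p = 0.131) and Insr (log2 0.12, adjusted p = 0.617) did not pass, while the receptor substrate Irs2 (log2 1.85, 76.6 CPM) and the adaptor Grb14 were the 2 members that were higher. Of 20 members tested, 13 were lower, also when adjusted over the list alone (camera adjusted p = 8.95e-07). That call was lost with an estimated correlation (adjusted p = 0.0917), and the call of Igfbp7, with 59.7 ± 77.2 CPM over the captures, was lost without the capture block (adjusted p = 0.317).

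Most G2 and M phase genes were higher in Sertoli-like cells than in the mean of the other classes. Without TMM scaling the list summed to 4865 ± 76.3 CPM in them, close to 4701 ± 237 in interstitial progenitor-like and 4436 ± 375 in peritubular myoid-like cells, and 1551 ± 309 CPM in fetal Leydig-like cells. The TMM factors of the captures were 0.995 and 0.978 in Sertoli-like and 0.955 and 0.944 in interstitial progenitor-like cells. Scaling would thus raise the interstitial sums by more, and the order of these 2 classes is not settled. In capture 2 interstitial progenitor-like cells had 4868 CPM against 4811 in Sertoli-like cells, and without a Sertoli-like cluster low in mitochondrial UMIs the Sertoli-like values were 4688 and 4303 CPM in the captures. Kif23 and Ect2, which act in cytokinesis, were 3.94-fold (127 ± 54.0 CPM) and 3.21-fold (25.8 ± 1.45 CPM) higher, and the proliferation marker Mki67 was higher by 1.05 on the log2 scale (63.5 CPM). Without TMM scaling Mki67 had 62.3 and 62.6 CPM in the captures, close to 51.6 and 54.7 in interstitial progenitor-like and 51.1 and 43.2 in peritubular myoid-like cells. Germ-like (8.74 and 7.64) and fetal Leydig-like cells (6.81 and 14.7) lay far lower. Some S phase genes were also higher, among them the repair enzymes Ung (2.67-fold, 85.8 ± 1.88 CPM) and Exo1 (2.40-fold). In the G2 and M list 41 of 52 members were higher and 3 lower (Hmgb2, Lbr and Tubb4b), 42 and 3 adjusted over the list alone. In the S list 20 of 42 were higher and 2 lower (Cdca7 and Prim1), 21 and 2 adjusted over the list alone. Both lists passed camera (adjusted p = 2.03e-06 and 0.00197). Both calls were lost with an estimated correlation (adjusted p = 0.410 for each).

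Cyclins and their inhibitors split by member. Ccnd2, the cyclin D2 gene, was higher in Sertoli-like cells (log2 1.90, 755 CPM), Mycn was 8.98-fold higher (97.2 ± 2.78 CPM), and the CDK inhibitor Cdkn1c was 10.9-fold lower (18.5 ± 5.38 CPM against 848 in fetal Leydig-like cells). With Cdkn1c, Ccnd1, Ccnd3, Ccne1 and Cdkn1b were the lower ones, against 13 of 27 higher, or 15 and 6 adjusted over the list alone (camera adjusted p = 0.459). After thinning to 3000 UMIs, 73.1% ± 1.11 of Sertoli-like cells had at least 5 UMIs of the G2 and M list, against 31.7% of fetal Leydig-like cells, which had the lowest list CPM, with median depths of 9944 and 15459 UMIs; without thinning the Sertoli-like share was 99.2%. Germ-like cells had 91.8% by the same count at only 3123 ± 238 CPM of the list, so no order of the classes was read from these shares.

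**Figure D2:**
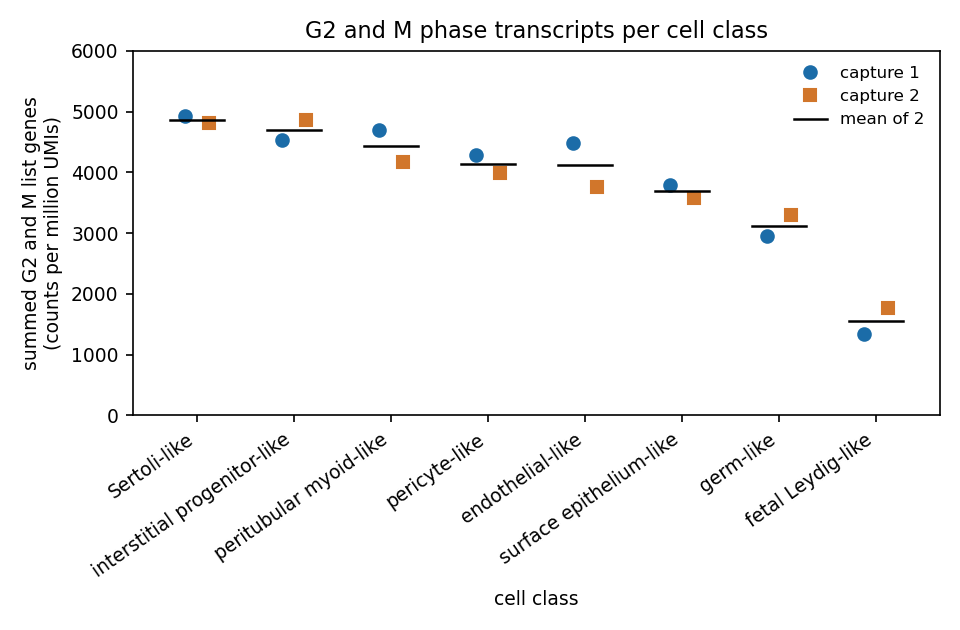
Summed CPM, without TMM scaling, of the 52 G2 and M phase list genes (vertical axis) in each of the 8 classes, with a circle for capture 1, a square for capture 2 and a horizontal line for their mean. On this scale class means lie between 1551 CPM in fetal Leydig-like and 4865 CPM in Sertoli-like cells, and in capture 2 interstitial progenitor-like cells (4868 CPM) lie above Sertoli-like cells (4811 CPM). The order of these 2 classes depends on the scaling.

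Junction genes were high and matrix genes low in Sertoli-like cells. Espn, an actin-bundling protein of the Sertoli cell junction, was 25.1-fold higher (172 ± 40.2 CPM), and Cgn, a tight junction protein, had 77.5 ± 16.2 CPM against 13.2 in the mean of the other classes. Of 17 junction genes 11 were higher and Cldn1 alone was lower, as adjusted over the list alone (camera adjusted p = 6.84e-05, but adjusted p = 0.156 with an estimated correlation). Of 22 basement membrane and matrix genes 14 were lower, led by Nid2 (14.4-fold, 2.31 ± 0.537 CPM), and 2 were higher, the laminin receptor Itga6 (12.7-fold, 227.5 ± 3.66 CPM) and Lama1, also adjusted over the list alone. This was the only list of the 20 that passed with the preset correlation (camera adjusted p = 3.27e-07) and with the estimated 1 (adjusted p = 0.0156).

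Single signalling genes were far higher in Sertoli-like cells, while of the Hedgehog, TGF-beta and Wnt lists the Hedgehog list alone passed camera, as lower. Dhh, the Hedgehog ligand of Sertoli cells, was 40.2-fold higher (194 ± 11.5 CPM), whereas 6 of 12 Hedgehog genes were lower, or 7 adjusted over the list alone, among them the coreceptor Boc (8.23-fold). The camera adjusted p of the Hedgehog list was 0.00555, but the adjusted p was 0.0917 with an estimated correlation. Inhbb, the activin and inhibin beta B subunit, was 29.4-fold higher (194 ± 10.5 CPM) and Amhr2, the receptor of anti-Müllerian hormone, had 98.7 ± 11.7 CPM against 8.76, in a list with 14 of 34 members higher and 14 lower (15 lower adjusted over the list alone; camera adjusted p = 0.459). Wnt6 was 19.4-fold higher (572 ± 133 CPM) and Sfrp1, a secreted Wnt antagonist, 10.4-fold lower, with 10 of 29 Wnt genes higher and 11 lower, as adjusted over the list alone (camera adjusted p = 0.345).

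Cholesterol synthesis genes were lower in Sertoli-like cells in 14 of 23 cases and higher in 3, Ldlr, Scap and Srebf1, which act in uptake and in control of the pathway, or 15 and 4 adjusted over the list alone. Mvd was 2.37-fold lower (16.2 CPM against 258 in fetal Leydig-like cells). The list passed camera (adjusted p = 6.52e-04) and not with an estimated correlation (adjusted p = 0.410). Receptor tyrosine kinases were lower in 13 of 22 cases, as adjusted over the list alone, including Kit (13.0-fold) and Ntrk3 (0.350 CPM against 21.6 in pericyte-like cells), and Axl, Ddr1, Erbb2, Erbb4 and Tyro3 were higher. That list stood just outside the threshold (camera adjusted p = 0.0619) and passed in 5 alternatives, such as without the capture block (adjusted p = 0.0172). The call of Ntrk3 was lost in thinned sums (adjusted p = 0.110) and with the highest doublet scores removed (adjusted p = 1.0).

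The other lists did not pass camera, though single members differed strongly. Aldh1a1, which makes retinoic acid, was 16.9-fold higher (1089 ± 41.6 CPM) and Stra6, a retinol transporter, had 29.7 ± 5.91 CPM against 4.31, with 3 of 13 retinoic acid genes higher, Cyp26b1 the third, and 6 lower (camera adjusted p = 0.30). The androgen receptor gene Ar was 5.84-fold lower (3.72 ± 1.46 CPM) and Ghr 7.38-fold lower, with 8 of 23 hormone receptors lower and 5 higher, Fshr, Nr1h2, Nr5a1, Rara and Thra (camera adjusted p = 0.460). Kitl, the ligand of KIT on germ cells, was 6.31-fold higher (66.0 ± 9.03 CPM), and of the ovarian supporting-cell genes Wnt4 (8.84-fold), Bmp2 and Cdkn1b were lower, 4 of 6 when adjusted over the list alone (camera adjusted p = 0.116). Hk2, a hexokinase, was 7.98-fold higher (233 ± 77.8 CPM) and Pfkl 2.16-fold higher, with 8 of 22 glycolysis genes higher and 6 lower (camera adjusted p = 0.693). The FoxO target Cited2 was 5.04-fold higher (439 ± 343 CPM) and Klf2 4.90-fold lower (19.2 ± 16.7 CPM), a call lost without the capture block (adjusted p = 0.189), with 8 of 17 higher and 7 lower (camera adjusted p = 0.693). Counts adjusted over the list alone were the same for these lists except the ovarian genes.

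Among mTOR genes the translation repressor Eif4ebp1 was 2.65-fold higher in Sertoli-like cells (378 ± 14 CPM) and Ddit4 was higher by 0.88 on the log2 scale, with 8 of 22 higher and 2 lower, Prr5 and Rps6, as adjusted over the list alone (camera adjusted p = 0.460). Notch genes were higher in 6 of 20 cases and lower in 9, or 10 adjusted over the list alone (camera adjusted p = 0.163). Notch3, a receptor of mural cells, was 6.26-fold lower, while Nrarp, at 25.7 ± 15 CPM, was above the geometric mean of the other classes and below the 197 CPM of endothelial-like cells. The dissociation stress list had 4 of 19 members higher, Hspb1 (9.26-fold, 714 ± 82.6 CPM), Ier3, Jund and Nr4a1, and 10 lower, or 11 adjusted over the list alone, with Socs3 7.67-fold lower (camera adjusted p = 0.0798). That list passed as lower in 2 alternatives, with no filter on low counts (adjusted p = 0.0346) and in thinned sums (adjusted p = 0.0470). The PI3K and TGF-beta lists had a median log2 above 0 and a mean below 0, and those 2 with the FoxO, hormone receptor and retinoic acid lists leaned up by fry and down by camera. Of the lists that did not pass camera, fry called as higher TGF-beta (adjusted p = 0.00180), FoxO (0.0203), retinoic acid (0.0118), glycolysis (0.00407), mTOR (0.00161), the cyclins (0.00300) and PI3K, and not the hormone receptors (0.0544).

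**Figure D3:**
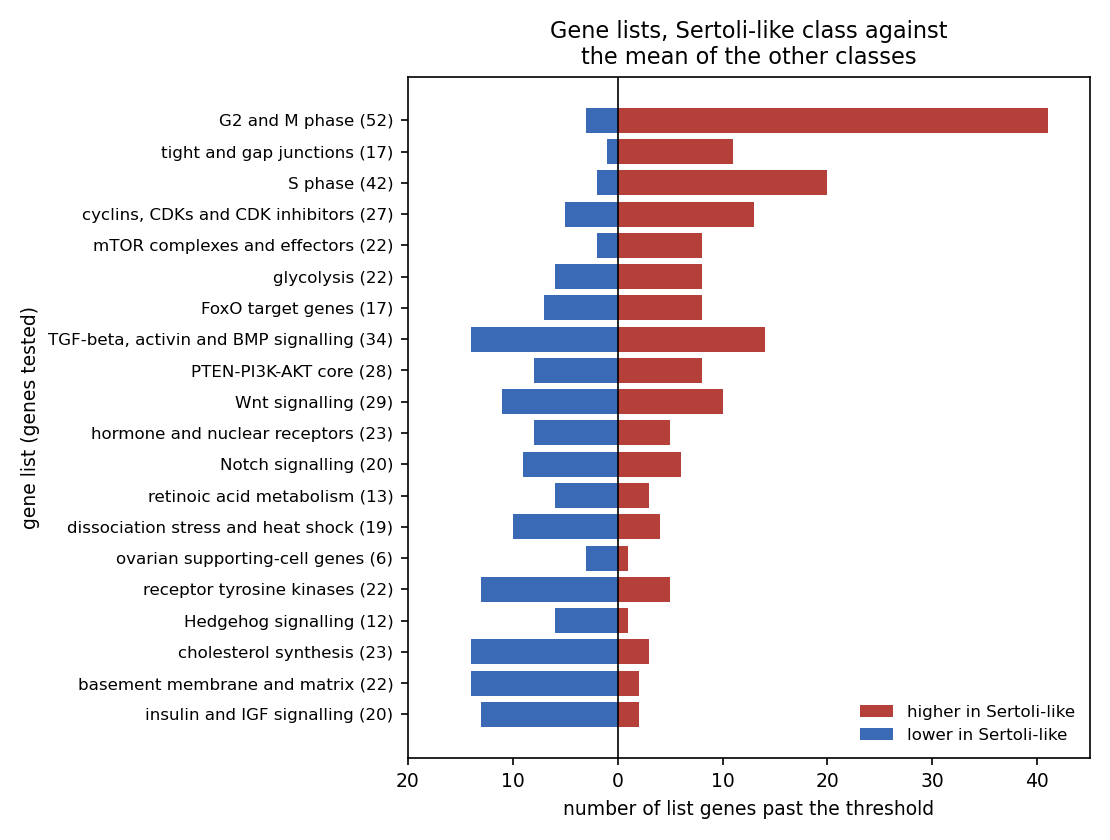
Number of tested members of each of the 20 gene lists that were higher or lower in the Sertoli-like class than in the mean of the other classes (horizontal axis, edgeR adjusted p under 0.05; red bars to the right are higher, blue bars to the left lower, and the number tested stands in brackets). G2 and M phase has 41 higher members and basement membrane and matrix 14 lower.

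The GFP transcript followed Nr5a1, which encodes a nuclear receptor of steroid-producing and supporting cells, in being highest in fetal Leydig-like and next in Sertoli-like cells. GFP had 10613 ± 5626 CPM in fetal Leydig-like, 1905 ± 1202 in Sertoli-like and 630 ± 335 in interstitial progenitor-like cells, down to 172 ± 102 in surface epithelium-like cells. Nr5a1 had 404 ± 14.8, 110 ± 3.75, 44.2 ± 2.08 and 14.2 ± 0.0829 CPM in the same classes. Fetal Leydig-like cells had 5.76-fold more GFP and 3.67-fold more Nr5a1 than Sertoli-like cells. Sertoli-like cells exceeded every other class of the fit, by 2.92-fold to 10.9-fold for GFP and by 2.49-fold to 7.73-fold for Nr5a1 (edgeR; GFP against the mean of all other classes log2 1.98, adjusted p = 3.75e-22). By CPM without TMM scaling, GFP was 2.16-fold to 2.66-fold higher in capture 1 than in capture 2 in each class, while the ratio for Nr5a1 lay between 0.776 and 1.17.

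**Figure D4:**
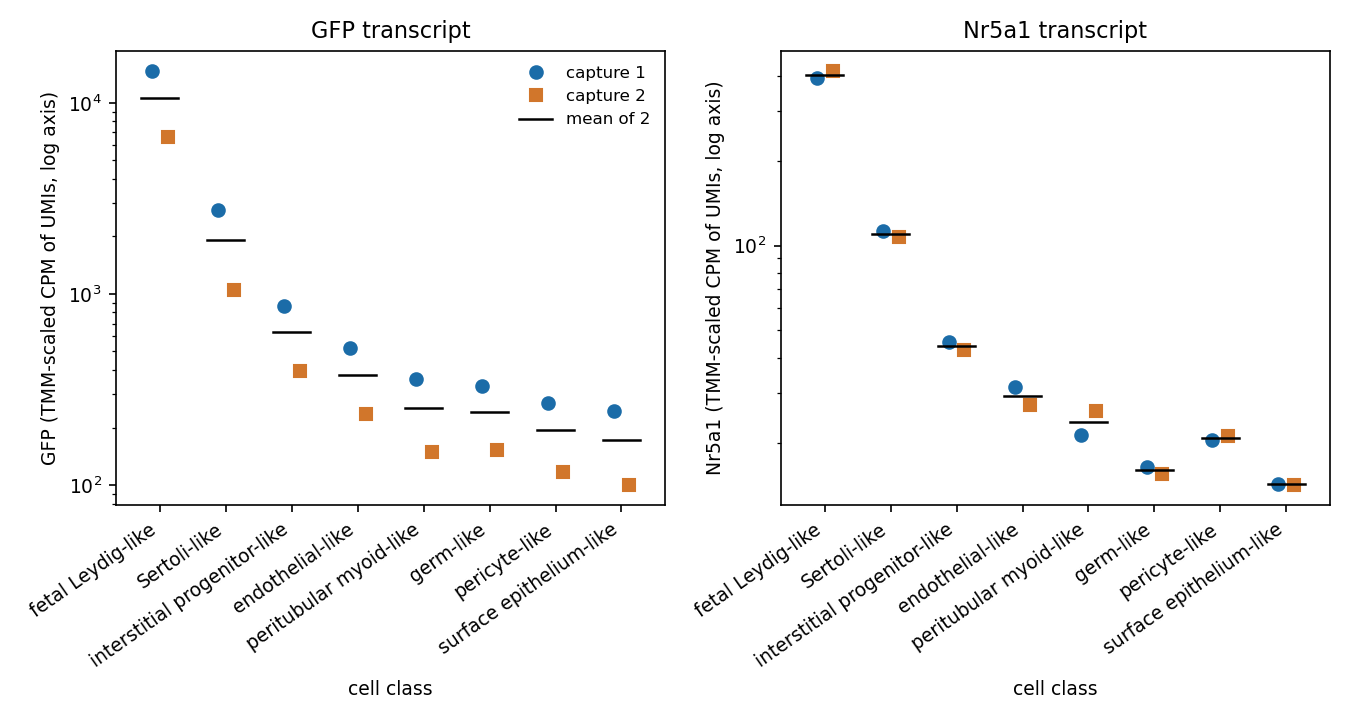
GFP (left) and Nr5a1 (right) in TMM-scaled CPM of UMIs (vertical log axes) in each of the 8 classes, with a circle for capture 1, a square for capture 2 and a line for their mean. Fetal Leydig-like cells lie highest, with means of 10613 CPM of GFP and 404 CPM of Nr5a1, followed by Sertoli-like cells.

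Fetal Leydig-like cells, which make androgens from cholesterol, had every one of 23 cholesterol synthesis genes higher than the other classes. Dhcr7, the last enzyme of the pathway, was 20.2-fold higher (648 ± 128 CPM), the inhibin alpha gene Inha 34.3-fold (2757 ± 37.5 CPM) and the retinoic acid-degrading enzyme gene Cyp26b1 25.0-fold (144 ± 14 CPM). The luteinizing hormone receptor gene Lhcgr had 201 ± 24.0 CPM against 1.45 in the mean of the other classes, the Hedgehog-binding Hhip 44.5 ± 16.1 against 8.15 and Aldoc 79.9 ± 17.5 against 9.30. Cell cycle genes were low: 48 of 52 G2 and M genes were lower and Kif2c alone higher, and all 42 S genes were lower. By camera the adjusted p was 7.17e-26 for cholesterol synthesis, 1.72e-24 for G2 and M and 2.26e-21 for S, and with an estimated correlation the adjusted p was 0.0464, 0.0781 and 0.0781. Adjusted over the list alone, 49 G2 and M genes were lower and the other counts were unchanged.

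Germ-like cells were low in matrix genes: 18 of 22 were lower, with Sparc 15.5-fold lower (166 ± 6.20 CPM), and Lama5 alone was higher (camera adjusted p = 1.74e-06, and adjusted p = 0.0387 with an estimated correlation). TGF-beta genes were lower in 23 of 34 cases and higher in 6 (camera adjusted p = 9.54e-04, and 0.0387 with an estimated correlation). Both counts were the same adjusted over the list alone. The dissociation stress list was low beside them, 17 of 19 lower and Hsp90aa1 and Hspa1b higher, as adjusted over the list alone (camera adjusted p = 6.18e-06, but adjusted p = 0.217 with an estimated correlation). The CDK inhibitor gene Cdkn2a was 60.1-fold higher (150 ± 11.4 CPM). Crabp1 had 111 ± 3.64 CPM against 5.85 in the mean of the other classes, Bcl6 21.9 ± 9.99 against 1.27, Met 21.7 ± 1.81 against 2.84 and Aldoc 42.8 ± 0.765 against 14.6. Of the 8 classes, germ-like cells differed from the mean of the rest in the most genes, 7311 higher and 5288 lower, or 3507 and 2849 in thinned sums. The median log2 of all tested genes was 0.28 in this class, a general shift upward.

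Endothelial-like cells were marked by Notch genes, 11 of 20 higher and Heyl and Notch2 lower, or 12 and 3 adjusted over the list alone. The ligand gene Dll4 had 81.7 ± 28.5 CPM against 0.584 in the mean of the other classes and Mfng 256.5 ± 8.40 against 3.28, and Nrarp was 50.3-fold higher (197 ± 148 CPM). No UMI of Cgn, Dkk3 or Hhip was seen in the class, which put them at least 11-fold, 4.88-fold and 6.60-fold below the arithmetic mean CPM of the other classes (floor of 3 UMIs over the class); the call of Hhip was lost in thinned sums (adjusted p = 1.0). Hedgehog genes were lower in 9 of 12 cases, with 1 higher when adjusted over the list alone (camera adjusted p = 4.98e-04, Notch 7.10e-07), and both lists held with an estimated correlation (adjusted p = 0.0357 for each).

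Interstitial progenitor-like cells were high in Hedgehog genes, 8 of 12, with Dhh alone lower, and in receptor tyrosine kinases, 13 of 22, with Ddr1 and Kit lower. Adjusted over the list alone, 9 Hedgehog genes were higher and the kinase counts were the same. The activin subunit gene Inhba was 14.7-fold higher (393 ± 26.8 CPM), Pdgfra 8.95-fold (265 ± 17.6 CPM) and Lama2 7.58-fold (59.2 ± 2.95 CPM). Hhip, a Hedgehog target, had 41.1 ± 2.46 CPM against 8.64 in the mean of the other classes, Ntrk1 70.9 ± 1.23 against 8.08 and Dkk3 26.5 ± 0.438 against 6.96. Both lists had a camera adjusted p of 4.09e-06, and an adjusted p of 0.0253 with an estimated correlation. The dissociation stress list was high beside them, 13 of 19 higher and Hsp90aa1, Hspb1 and Ier3 lower, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.00195, but adjusted p = 0.331 with an estimated correlation).

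Pericyte-like cells, the mural cells of small vessels, were high in matrix genes, 14 of 22, with Hspg2 alone lower, and in Notch genes, 8 of 20, with none lower. Adjusted over the list alone these were 17 and 2, and 10 and 0. Heyl was 30.2-fold higher (330 ± 7.25 CPM), Pdgfrb 22.5-fold (244 ± 12 CPM), Notch3 18.5-fold (150 ± 12.1 CPM) and Hey2 14.9-fold (42.6 ± 3.69 CPM). Camera gave an adjusted p of 6.92e-15 for matrix and 1.66e-06 for Notch, and with an estimated correlation the adjusted p was 0.00180 and 0.0350. Aldoc and Met had no UMI in the class and were at least 13.9-fold and 3.98-fold below the arithmetic mean CPM of the other classes; the call of Met was lost in 6 alternatives, with an adjusted p of 0.0669 without the capture block.

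Peritubular myoid-like cells had 13 of 20 insulin and IGF genes higher and Grb14, Igfbp7 and Insr lower (15 and 3 adjusted over the list alone; camera adjusted p = 5.23e-06, but adjusted p = 0.107 with an estimated correlation). Sfrp1 was 9.01-fold higher (1003 ± 637 CPM), and Gas1 9.22-fold (428 ± 410 CPM), while Itga6 was 7.37-fold lower (4.36 ± 0.753 CPM). Cldn1 had 29.9 ± 3.98 CPM against 6.02 in the mean of the other classes and Ntrk3 17.7 ± 1.70 against 5.0. Dll4, the sixth gene named by the rule, had 1 UMI in the class, and its call was lost in 4 alternatives, such as DESeq2 (adjusted p = 0.0611). Surface epithelium-like cells had 17 of 29 Wnt genes higher and Tcf7 and Wnt6 lower, and 19 of 34 TGF-beta genes higher and Inha, Inhba and Tgfb1 lower (19 and 4, and 21 and 4, adjusted over the list alone). Camera adjusted p-values were 2.13e-06 and 7.27e-06, and both lists held with an estimated correlation (adjusted p = 0.00944 for each). The dissociation stress list was high beside them, 14 of 19 higher and 0 lower, as adjusted over the list alone (camera adjusted p = 5.25e-10, but adjusted p = 0.0611 with an estimated correlation). Sfrp2 was 46.6-fold higher (294 ± 29.0 CPM), Lama5 24.3-fold (55.9 ± 0.669 CPM) and Igfbp5 16.8-fold (1071 ± 119.9 CPM). The activin-binding Fst had 76.8 ± 68.4 CPM against 3.06, Aldh1a2 254 ± 35.7 against 20.6 and Cgn 49.1 ± 11.4 against 17.2. Over the 7 classes other than Sertoli-like, 60 of 140 list tests passed camera with the preset correlation and 15 with an estimated correlation.

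The captures resembled each other within every class, with Pearson r across genes of log2 CPM between 0.898 in endothelial-like and 0.982 in interstitial progenitor-like cells; genes are not independent replicates. Of 1551 genes with at least 50 CPM in every class in at least 1 of the captures, 45 were at least 2-fold higher in capture 1 in all 8 classes by the ratio of CPM plus 5, among them H1fx, Jund, Taf10, Igfbp7, GFP, mt-Co3 and mt-Atp6. Another 4 were at least 2-fold higher in capture 2 in all 8 classes: Uba52, Glo1, Gm1821 and Gm10076. In single classes 4.02% of genes (germ-like) to 8.01% (pericyte-like) lay at least 2-fold apart. With 1 sample per capture these differences have no test.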

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

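The cells outside the 8 classes of the fit had UMIs of both transcripts of main interest, above the limit that a count of 0 allows. Neither free RNA nor shared droplets were subtracted, and no explanation was tested for these values. CPM values here are without TMM scaling, unlike those of the contrasts between clusters below. The unnamed stromal cluster had 70.6 ± 39.2 CPM of Pten and 546 ± 356 CPM of GFP (mean ± SD, n = 2 captures). It entered contrasts chosen after seeing the data. The duct or rete epithelium-like cells had 56.2 ± 13.9 CPM of Pten and 1730 ± 1117 CPM of GFP. The white blood cell-like cells had 48.4 ± 15.6 CPM of Pten and 662 ± 743 CPM of GFP, and these last 2 classes rest on 18 and 21 and on 15 and 36 cells and entered no test, so their values are not read as expression. In the white blood cell-like cells GFP was 136.7 and 1187 CPM in the captures, and the median doublet scores were 0.0469 and 0.0560. In them 9 fetal Leydig markers were at least 2-fold above the mean of the clusters other than fetal Leydig-like. The duct or rete epithelium-like cells had 8 Sertoli markers at least 2-fold above the mean of the clusters other than Sertoli-like, and median doublet scores of 0.0561 and 0.0508.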

How the results depend on the processing

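The alternatives that remove the highest doublet scores, drop the last naming condition or remove the 2 clusters low in mitochondrial UMIs were chosen after seeing the data; the others were fixed before. Among the results rerun in the alternatives, none that passed its test turned in direction. List tests were rerun for the Sertoli-like contrast alone. The pairwise contrasts of GFP and Nr5a1 and the contrasts between clusters were not rerun. Higher calls outnumbered lower ones except with DESeq2 (3512 higher, 3562 lower). Sertoli-like genes higher and lower stayed within 1.5 times of the reported counts except in sums thinned to the smallest total (1802 and 1283 of 9776 genes tested), where fewer counts entered. The share of calls that were higher was 74.4% at clustering resolution 2 (5675 higher, 1955 lower) and 72.9% without the low-mitochondrial clusters (5572 and 2073). Pten against the mean of the other classes passed in 0 of 14 tested alternatives, with log2 from −0.07 to 0.24 and adjusted p-values from 0.218 to 1.0 (edgeR and DESeq2); its sign turned with RLE, DESeq2, centring and capture 2 left out (−0.11).

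Pten in Sertoli-like against germ-like cells lost its call with RLE (0.19), total counts (0.37), no replicate block (0.57, adjusted p = 0.968), DESeq2 (0.19), thinned sums (0.48), centring within captures (0.19) and the highest doublet scores removed (0.54, adjusted p = 0.0539); with 1 capture left out the value was 0.56 and 0.56, with no test. Against surface epithelium-like cells the range with 1 capture left out was 0.25 to 0.27. The cause was not tested.

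Of the PTEN-PI3K-AKT list, 5 members were higher and 5 lower without the capture block, 5 higher with DESeq2, 4 higher and 1 lower in thinned sums, and 5 lower at resolution 2 and without the low-mitochondrial clusters. In the insulin and IGF list 4 were higher in those last 2 settings. In the G2 and M list 26 were higher in thinned sums, and 1 was lower without the block and at resolution 2. The block is a term for the capture and not a pairing of groups.

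The Sertoli-like share was 21.3% with the highest doublet scores removed and 18.0% without the low-mitochondrial clusters, which took the germ-like share to 4.11%. The interstitial share was 40.4% at resolution 0.5, 35.7% at resolution 2 (44.7% and 26.7% in the captures), 35.1% after centring (39.2% and 31.1%) and 32.9% without the filters on genes and mitochondrial UMIs per cell (42.4% and 23.4%). In the same order the peritubular myoid-like share was 22.3%, 6.62%, 9.74% and 13.2%, and it was 11.9%, 19.9% and 12.7% in the 3 added alternatives. The pericyte-like share was 0.887% after centring. The share of Sertoli-like cells with G2 and M UMIs was set by depth and minimum: 48.2% at 1500 UMIs, 96.8% at 6000, 99.2% unthinned, 90.6% at 3 UMIs, 45.2% at 10, and 71.4% without the low-mitochondrial cluster.

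Among single genes named for Sertoli-like cells, 931 values stayed the same, 37 without a test moved, and 8 lost the call. Values with a capture left out have no test, and those among the 931 stayed within the SD of the captures. Each of 2 captures lies within that SD of their mean by arithmetic, so these values decide nothing about stability. For the other classes 576 kept direction and call and 11 lost the call, and of their counts of genes 163 stayed within 1.5 times and 33 did not. Of the list tests in the Sertoli-like contrast 252 kept their side, 7 gained a call and 1 lost it, the Hedgehog list with the highest doublet scores removed (camera adjusted p = 0.111). Depth limited the calls of scarce genes, since thinned sums left 9776 genes to test.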

Other observations

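The contrasts between clusters, the marker ratio for GFP, the tests of the capture difference and the test of mitosis were chosen after the result was seen; the Malat1 test and the germ-like G2 and M test were written before it.

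Within the Sertoli-like class, a cluster of 86 and 212 cells was high in G2 and M genes and low in stress genes. Against the other Sertoli-like clusters it had 1996 genes higher and 3267 lower of 15796 tested (edgeR; median log2 of all tested genes −0.35, a general shift downward), with Cdk1 at 524 ± 133 against 101 ± 6.76 CPM (n = 2 captures). In the G2 and M list 26 of 52 members were higher and 8 lower, 27 and 8 adjusted over the list alone (camera adjusted p = 4.36e-07, but adjusted p = 0.315 with an estimated correlation). The other Sertoli-like clusters were not uniform in this list. In capture 2 its CPM was 7151 in a cluster of 365 cells and 1968.5 in a cluster of 634, against 9235 in this cluster. Of 19 stress genes 14 were lower and Hspb1 higher, 15 and 1 adjusted over the list alone (camera adjusted p = 9.33e-05, but adjusted p = 0.173 with an estimated correlation). Pten was lower, at 19.2 ± 8.57 against 44.6 ± 7.14 CPM (log2 −1.30, adjusted p = 0.00342), from only 13 and 16 UMIs in this cluster. So were 12 of 27 tested PTEN-PI3K-AKT members with 0 higher, 13 and 1 adjusted over the list alone (camera adjusted p = 0.00309, but adjusted p = 0.132 with an estimated correlation). By camera with the preset correlation other lists fell there too, among them Wnt (14 of 28 lower), TGF-beta (13 of 34) and matrix (10 of 22). Glycolysis rose (11 of 22 higher). The fall was thus not particular to the PI3K list. Median UMIs per cell were also low in this cluster, 6354 and 6171, against 10459 in the main other cluster of capture 1 and 9722 and 13331 in those of capture 2. In a germ-like cluster of 33 and 80 cells, also low in mitochondrial UMIs, 13 of 27 members of the PTEN-PI3K-AKT list were lower and 1 higher than in the other germ-like cluster, as adjusted over the list alone (camera adjusted p = 1.81e-04, and adjusted p = 0.0218 with an estimated correlation), among 2769 genes higher and 2730 lower. Pten did not pass there (log2 −0.62, adjusted p = 0.110). The matrix list had the same camera adjusted p-values in that contrast, with 13 of 22 members lower and 0 higher. Insulin and IGF (camera adjusted p = 0.0075) and receptor tyrosine kinase genes (0.0118) were among the other lists that passed as lower with the preset correlation. Glycolysis (0.0200) and S phase (0.0368) passed as higher. The unnamed stromal cluster differed from interstitial progenitor-like cells in 239 genes higher and 304 lower and was low in 42 of 52 G2 and M genes, 49 adjusted over the list alone (camera adjusted p = 1.09e-63, and adjusted p = 0.0112 with an estimated correlation). That level rested on 1 of the 5 interstitial progenitor-like clusters, with 11374 and 11535 CPM of the list in the captures; the other 4 had 1359 to 2078 CPM, under the 2741 and 2134 of the unnamed cluster. Against peritubular myoid-like cells it had 672 higher and 809 lower, and more Pten (72.5 ± 41.2 against 40.8 ± 18.5 CPM, log2 0.80, adjusted p = 0.0144). Pten did not pass against interstitial progenitor-like cells, where 0 of 27 tested PTEN-PI3K-AKT members were higher and 0 lower.

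GFP per summed CPM of 5 Leydig marker genes (Insl3, Cyp17a1, Cyp11a1, Hsd3b1 and Star) was 0.653 and 0.255 in fetal Leydig-like cells of the captures. In germ-like cells it was 1.23 and 1.03 times that ratio, in surface epithelium-like cells 2.95 and 2.93 times, in interstitial progenitor-like cells 11 and 9.96 times and in Sertoli-like cells 29.7 and 25.7 times.

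In both captures, that Sertoli-like cluster and that germ-like cluster had a low share of mitochondrial UMIs: 0.663% and 0.805% against 2.26% and 2.61% in the other Sertoli-like clusters, and 0.0960% and 0.108% against 1.93% and 2.04% in the other germ-like cluster. Cells in mitosis stay open in both clusters. In the germ-like cluster the G2 and M level was 1.27 and 1.43 times that of its neighbour. These values fell under a bound set after they were seen, so that bound decides nothing. Between the germ-like clusters 13 of 52 list members were higher and 7 lower. The list leaned up and did not pass camera (adjusted p = 0.280, and adjusted p = 0.884 with an estimated correlation). In the Sertoli-like cluster the level was 1.64 and 2.15 times that of the others pooled. Those others were mixed in capture 2, where a cluster of 365 cells had 7151 CPM of the list against 9235 in the low-mitochondrial cluster. Droplets with cytoplasm and no nucleus may lie behind the pattern and stay open: Malat1, a nuclear RNA, was 23.0-fold and 29.97-fold lower in the Sertoli-like cluster, but in the germ-like cluster 10.6-fold and 3.28-fold lower, and the last value misses the 4-fold set beforehand. Neat1 and Kcnq1ot1, other nuclear RNAs, were also lower in both clusters and both captures, by unlike amounts. Neat1 was only 2.19-fold and 1.73-fold lower in the germ-like cluster, and had 1.74 and 4.23 CPM against 17.5 and 66.3 in the Sertoli-like clusters. Kcnq1ot1 had 1.19 and 2.37 CPM against 24.6 and 26.3 in the germ-like and 1.74 and 4.93 against 126 and 118 in the Sertoli-like clusters, from 1 to 7 UMIs each. No other biological explanation was tested.

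For the 49 genes at least 2-fold apart between captures in all 8 classes, GC content near the 3' end was examined. With all genes grouped by GC content, group medians of the log2 ratio ran from −0.11 to 0.08. Among the 46 with a GC value the smallest median in size was −1.16 (Gm10076), so this general trend was too small to account for them. That 100% of the 46 stayed 2-fold apart without the trend follows from these sizes and decides nothing further. An effect of GC content on single genes stays open. Across genes Spearman rho of the median log2 ratio was 0.22 with GC content and −0.33 with transcript length, which was not tested further. Handling stress before lysis stays open: 2.04% of these genes (Jund alone) were on the stress list, but with 8 of its members at that level it could reach at most 16.3%, so the share decides nothing, and its median log2 differed by at most 0.65 in size in any class. Reads shared with pseudogenes could account for part: 22.4% of these genes (11 of 49) were pseudogenes against 4.38% of all genes at that level (Fisher's exact test, two-sided, p = 3.95e-06), which met the prediction as worded but leaves the other genes open; the bound for the set as a whole, more than 50% of its genes, was set after the result was seen. A difference between the sequencing runs cannot be told apart from the captures themselves, and no biological explanation was tested.

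Germ-like cells had the highest share of cells with G2 and M UMIs of the 8 classes at a low list CPM. A few abundant genes of the list may be the reason: Tubb4b, Cks2, Hmgb2, Anp32e and Cenpf held 49.5% and 51.3% of the list's UMIs in the class. Without these 5 genes 47.5% of germ-like cells kept at least 5 UMIs (44.7% and 50.3% in the captures), under the 56.9% and 59.8% of Sertoli-like cells, so the germ-like share was then not the highest, though these genes were picked in germ-like cells. The value lay between the bounds set beforehand of under 10% and over 50%, so the explanation stays open, and the depth of germ-like cells is removed by the thinning.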
